A study of Mus musculus with 9 samples.

How the data were processed

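Total RNA of inguinal white adipose tissue was hybridised to Affymetrix Mouse Transcriptome Array 1.0, with 1 array per sample and biotin as the label, per the labels. The values analysed are the log2 values that the authors deposited for 72688 rows on 9 arrays. Per the submitters' processing notes they were made with Affymetrix Expression Console, and its version, the summarisation and normalization method and the genome build are not given in the sources used here. That the scale is log2 was taken from the values, which run from 1.84 to 19.93, with 25th, 50th and 75th percentiles that nearly coincide between arrays and a shared upper end near 19.93. The upper end compresses differences of the brightest genes: 209 of the tested genes had a mean above 18. On 487 rows all 9 arrays held the same value, and 66 of these were among the tested genes. The values carry no count or detection call. The number of arrays limits the precision.

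Rows were named through the platform annotation deposited in the public archive, of which 65770 are transcript clusters. Of these, 31051 name 1 gene symbol, 1534 name several and 33185 name none; 1439 symbols were updated through the Entrez gene ID with the RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only. The other 6918 rows are control or unmapped rows and were left out. As no build is named for the values, no coordinates are given. Rows with 1 symbol were kept where the row mean over all 9 arrays was at or above the median of the row means of the whole table (5.31), and of several rows of a gene the row with the highest mean was kept, which left 16898 genes from 17083 rows. Some symbols, such as those of pseudogenes, share sequence with other genes, and the array cannot part them.

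The groups were taken from the labels: 3 control arrays at room temperature, 3 knockout arrays at room temperature and 3 control arrays from the cold. The log2 values were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, trend and robust off) over all 9 arrays with 3 group means, 6 residual degrees of freedom and 1.23 prior degrees of freedom. The 3 differences between groups were tested two-sided and the 3 groups together with the F test, each with Benjamini-Hochberg adjustment over 16898 genes and a threshold of 0.05. Errors of log2 fold changes are the moderated standard errors of this fit. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists of a comparison, and again with an estimated correlation. Under the latter, 0 of the 29 lists passed in any of the 3 comparisons (2, 5 and 1 lists at an unadjusted p under 0.05 for knockout against control, cold against control and cold against knockout). For the lists that passed, members past the threshold over all genes and those past it when adjusted over the list alone are counted separately. In none of the lists that passed did the mean, the median and the direction of the test differ in sign; among all 29 lists they did so in 8, 2 and 3 lists. The similarity of the knockout and cold effects was measured as the correlation and covariance of their log2 fold changes, with 100 simulated pairs of unchanged groups against shared controls. The overlap of genes past the threshold and the same-sign counts were set beside 100 further simulations, each fitted like the data, once with the genes past the threshold and once with the genes of smallest p taken in the observed number for each direction, whether or not they passed. Both sets of simulations drew each gene independently, while genes in the data varied together. The further simulations were added after the data were seen.

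The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named are Zfp423, Ucp1, Cidea, Dio2, Ppargc1a, Elovl3, Prdm16, Ebf2, Lep, Adipoq and Pparg. For each comparison against control the rule adds the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold whose arrays did not overlap, and 5 and 5 for cold against knockout. Of each list it adds up to 4 members past the threshold with the largest change, or up to 2 members as values where none passed. Predicted and unnamed symbols, small RNA genes, olfactory and vomeronasal receptors and immunoglobulin or T cell receptor segments were left out of the ranked genes, and sex-linked genes are given only with the sex-linked list. Where fewer than 5 genes passed in a direction, those that passed and the 5 with the smallest p were to be named, which did not arise.

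The fit was tested on simulated data with 50 genes changed at each size. In simulated knockouts it recovered 32%, 80%, 92% and 96% of genes changed by 0.5, 1, 2 and 3 log2 units, and 8 of 164 calls fell on unchanged genes; in simulated cold groups it recovered 42%, 82%, 100% and 100%, with 13 of 181 calls on unchanged genes. These simulations drew the arrays of a group independently. Alternatives were quantile normalization, centring of each array on its median, no filter, a filter at the 75th percentile of row means (7.39), the mean of all rows of a gene, all transcript clusters each for itself, a prior with trend and robust on, and array weights. Further alternatives were the 2 compared groups alone, the replicate number as a block, each array left out in turn, other thresholds, and for lists the estimated correlation and the directional fry test. Added after the data were seen were fits without the array of each group that lay between the other 2, and without the rows that hold 1 value on all arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.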

Results

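Gene expression was measured in inguinal white adipose tissue, the subcutaneous fat pad of the groin, of adult mice. The design asked how similar the tissue of mice that lose Zfp423 in adipocytes is to the tissue of cold-exposed controls, in which thermogenic beige adipocytes form. Zfp423 is a zinc finger transcription factor that keeps white adipocytes in their white state. Control mice carried a doxycycline-responsive activator driven by the adiponectin promoter and an inducible Cre recombinase, and knockout mice carried the same transgenes with both Zfp423 alleles floxed. Doxycycline started at 8 weeks of age and lasted 28 days in all groups. The 3 groups were controls at room temperature, knockouts at room temperature and controls that spent the last 14 of these days at 6 °C, with 3 arrays in each. All 9 arrays were of 1 platform, and their number limits the precision. The label of cold replicate 3 has a slightly different prefix from the other labels, and whether this marks another batch is not stated. The labels do not say whether the arrays of a group came from separate mice, so the p-values measure only the spread between these arrays, which may be partly technical. In each group 1 array lay between the other 2 for most genes, as described at the end, and each count of changed genes is given without these arrays as well. Leaving out the arrays nearest their group means raises the spread within groups by construction and leaves fewer residual degrees of freedom. A lower count without them therefore does not by itself show instability. If these arrays hold a mix of the RNA of the other 2, which is not excluded, the counts with them rest on too small a spread.

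Zfp423 itself had a mean log2 expression of 8.45 ± 0.27 (SD, n = 3) in controls, 7.92 ± 0.31 in knockouts and 8.65 ± 0.22 in cold-exposed controls. The knockout arrays read 7.56, 8.15 and 8.04 and the control arrays 8.74, 8.22 and 8.40, so the groups did not overlap. The difference of -0.53 ± 0.20 (SE) log2 units did not pass the threshold over all genes (limma adjusted p = 0.255), and the exact permutation test of 3 against 3 gave a two-sided p of 0.1, the smallest this design allows. The tissue was the whole fat pad, and the inducible Cre depends on a transgene named for the adipocyte gene Adiponectin, so cells other than adipocytes may keep the gene. Over the 21 alternatives the difference ranged from -0.65 to -0.36 and the adjusted p from 3.66e-05 to 0.949, and it passed in 1 of them, with array weights. Where the probes of this row lie relative to the floxed part is not given in the sources used here, so the row is a weak check of the labels.

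The knockout tissue expressed genes of thermogenic fat at levels far above those of the controls. Ucp1, the uncoupling protein of brown and beige adipocytes, rose by 6.90 ± 0.47 (SE) log2 units, from 12.4 ± 0.66 (SD, n = 3) to 19.3 ± 0.85 (limma adjusted p = 0.00863). The muscle-type fatty acid binding protein Fabp3 rose by 7.54 ± 0.94, the carnitine palmitoyltransferase Cpt1b by 4.87 ± 0.51, the cytochrome c oxidase subunit Cox7a1 by 4.29 ± 0.34 and the lipid droplet protein Cidea by 3.40 ± 0.36 (limma adjusted p between 0.0126 and 0.0373). The fatty acid transporter Slc27a2 rose by 3.81 ± 0.54 and the proton channel Otop1 by 3.53 ± 0.48 (limma adjusted p = 0.0469 for both). The row of Fabp3-ps1 rose by 8.24 ± 1.07, and as a pseudogene of Fabp3 it may share probes with it. Of the 32 measured members of the thermogenic list, 12 rose, 0 fell and 20 did not pass, and 22 rose when adjusted over the list alone. Their mean shift was 2.34 (camera adjusted p = 3.45e-17, and adjusted p = 0.446 with an estimated correlation). Ucp1 reached 19.92 in knockout replicate 2, close to the highest value of the table, 19.93, so its change there is bounded from above by the scale.

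Other genes of the thermogenic program differed widely among the 3 knockout arrays. Dio2, which activates thyroid hormone, read 7.65, 13.19 and 11.54 in knockout replicates 1, 2 and 3 against a control mean of 5.90 ± 0.16 (SD, n = 3), and Ppargc1a, a coactivator of mitochondrial genes, read 9.77, 13.80 and 12.40 against 8.70 ± 0.16. Neither passed, nor did the fatty acid elongase Elovl3 at 4.44 ± 1.00 (SE), with limma adjusted p of 0.126, 0.143 and 0.0965. The transcription factors Prdm16 and Ebf2 differed from control by 0.33 ± 0.18 and 0.19 ± 0.16 and did not pass (limma adjusted p = 0.424 and 0.594). The adipocyte genes Adipoq, Pparg and Lep stood at -0.46 ± 0.10, -0.49 ± 0.22 and -1.13 ± 0.74, and none passed (limma adjusted p = 0.0965, 0.343 and 0.495).

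**Figure D1:**
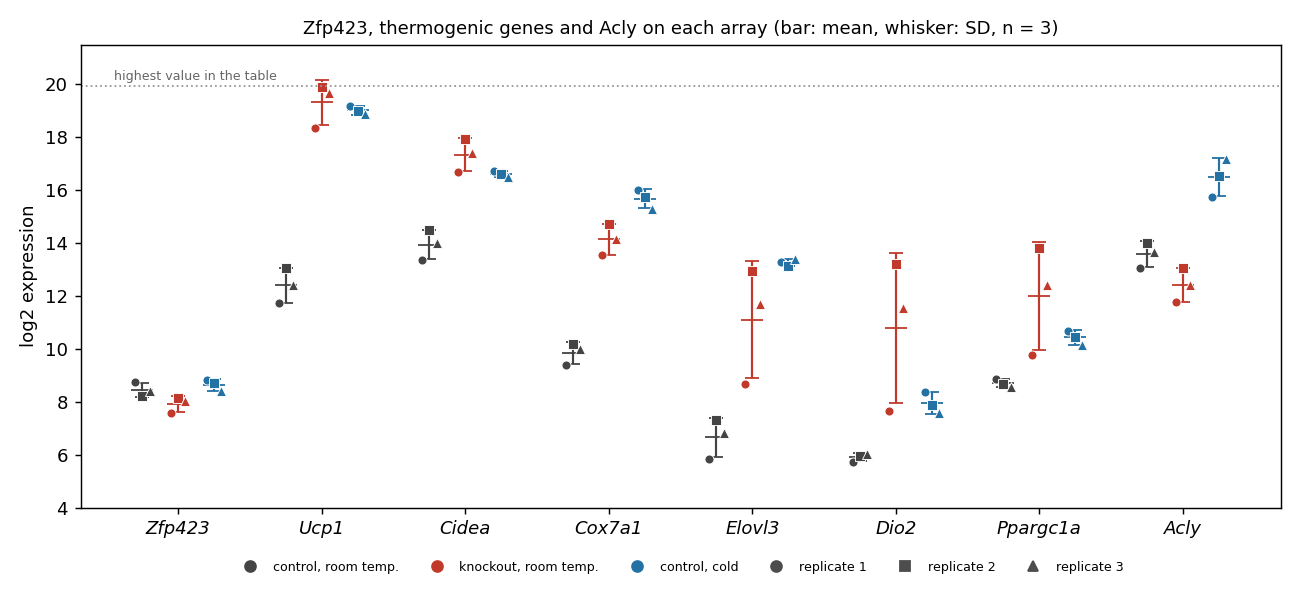
Log2 expression (y axis) of Zfp423, 6 thermogenic genes and the lipogenic gene Acly on each of the 9 arrays, with group means as bars and SDs (n = 3) as whiskers. Ucp1 lies between 18.34 and 19.92 in the knockouts and between 18.86 and 19.18 in the cold-exposed controls, while Dio2 spans 7.65 to 13.19 within the knockouts.

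Genes of fuel oxidation were also higher in the knockouts. In the citric acid cycle list, 3 of 18 members rose and 0 fell, namely the succinyl-CoA synthetase subunit Sucla2 (2.11 ± 0.23) and the isocitrate dehydrogenase subunits Idh3b (0.84 ± 0.12) and Idh3g (0.61 ± 0.06). Of the list, 14 rose when adjusted over the list alone. In the fatty acid oxidation list, 4 of 24 rose and 0 fell, among them Acadvl (2.12 ± 0.26) and Acaa2 (1.76 ± 0.16), beside Hadhb and Eci1. Of this list, 16 rose and 1 fell when adjusted over the list alone. Of 52 measured subunits of oxidative phosphorylation, 0 passed over all genes, with Cycs at 1.87 ± 0.42 and Sdhd at 1.83 ± 0.34 as the largest differences, and 48 rose and 1 fell when adjusted over the list alone. The list means were 0.99, 0.80 and 0.85 log2 units (camera adjusted p = 4.79e-12, 1.76e-10 and 5.99e-27, and adjusted p = 0.446, 0.481 and 0.446 with an estimated correlation). Pdk4, a kinase that restrains pyruvate oxidation, rose by 3.23 ± 0.41 (limma adjusted p = 0.0376). It belongs to the thermogenic list and to the glucocorticoid and starvation list, of whose 14 members it was the 1 that passed.

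The ranked genes with the largest falls in the knockouts were Chst1, a sulfotransferase (-2.34 ± 0.28), the galactosyltransferase B3galt2 (-1.98 ± 0.20) and the glutamate transporter Slc1a3 (-1.96 ± 0.24). They were followed by the metalloreductase Steap4 (-1.95 ± 0.21), the nuclear membrane protein gene Tmem43 (-1.62 ± 0.19) and Hcar2, the niacin receptor that restrains lipolysis (-1.56 ± 0.16). Fam102b and Fry followed with -1.47 ± 0.20 and -1.34 ± 0.17, and limma adjusted p for these 8 genes lay between 0.0251 and 0.0469. Of the lipogenesis list, 0 of 24 members rose and 1 fell, the row named Agpat9 (-0.80 ± 0.11, limma adjusted p = 0.0469). The annotation gives this row 2 Entrez genes, 1 of them Gpat3, whose own row stood at -0.19 and did not pass (limma adjusted p = 0.831). Adjusted over the list alone, 1 rose and 8 fell. The list mean was -0.38 (camera adjusted p = 0.000922, and adjusted p = 0.671 with an estimated correlation), and without knockout replicate 1 it was -0.11 with a camera adjusted p of 0.466. The general adipocyte list stood at -0.51 and the white adipocyte list at -0.64, with 0 members past the threshold in either. The hormone receptors Tshr (-2.03 ± 0.55) and Npr3 (-2.51 ± 0.99) had the largest differences, and 6 and 4 members fell and 0 and 1 rose when adjusted over each list alone. The extracellular matrix list stood at -0.49, again with 0 members past the threshold, Col1a1 at -1.30 ± 0.44, and 8 lower when adjusted over the list alone. These 3 lists passed (camera adjusted p = 5.93e-06, 5.74e-05 and 3.45e-08, and adjusted p = 0.597, 0.597 and 0.446 with an estimated correlation).

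Markers of other cell types varied among the knockout arrays together with these groups, and immune markers also varied among the room temperature control arrays. The T cell list was higher in the knockouts by 0.64 on average with 0 of 19 members past the threshold and 1 when adjusted over the list alone (camera adjusted p = 2.23e-05, and adjusted p = 0.671 with an estimated correlation). Relative to the control mean it stood at 1.29, -0.11 and 0.75 in knockout replicates 1, 2 and 3, while the thermogenic list stood at 1.53, 3.04 and 2.45 and the general adipocyte list at -0.83, -0.21 and -0.48. The macrophage list stood at 0.57, -0.87 and 0.00 and the skeletal muscle list at -1.24, 0.28 and -0.29 on the same arrays, and neither passed between the groups (camera adjusted p = 0.0993 for both). In control replicates 1, 2 and 3 the macrophage list stood at -0.47, 0.47 and 0.00 and the T cell list at -0.23, 0.26 and -0.03. The B cell list stood at -0.72, 0.71 and 0.00 there, and at 0.51, -0.77 and -0.07 in knockout replicates 1, 2 and 3. The macrophage list passed without control replicate 1 or knockout replicate 1 (camera adjusted p = 0.00224 and 0.000619, at -0.33 and -0.43), and the muscle list without knockout replicate 2 (0.00866, at -0.76) or cold replicate 1 or 3 (0.0434 and 0.00333). The B cell list stood at -0.11 (camera adjusted p = 0.472) and passed without control replicate 1 (0.00303, at -0.47) or knockout replicate 1 (0.0448, at -0.42). The endothelial list stood at -0.12 (camera adjusted p = 0.158) and passed without control replicate 2 (0.0184, at -0.23) or knockout replicate 2 (0.0023, at -0.26). The cell cycle list stood at 0.13 (camera adjusted p = 0.129) and passed without the same arrays (0.0391, at 0.20, and 0.00042, at 0.25). The circadian clock list stood at -0.20 with 0 of 17 members past the threshold and 3 when adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.446 with an estimated correlation). Without knockout replicate 1 it stood at -0.16 with a camera adjusted p of 0.112.

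In all, 62 of 16898 genes passed between knockouts and controls, 38 higher and 24 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 10 of 29 gene lists passed, 5 higher and 5 lower (0 lists with an estimated correlation, 2 at an unadjusted p under 0.05, and 4 by the fry test). The arrays of the 2 groups did not overlap for 17.3% of the genes, against 10% by chance. Without the 3 arrays that lay between the other 2 of their group, left out after the data were seen, limma called 0 genes (689 at an unadjusted p under 0.05), with a larger spread within groups by construction. Leaving out 1 array at a time gave 1, 340 and 1 genes without control replicates 1, 2 and 3, then 833, 37 and 0 without knockout replicates 1, 2 and 3, and 10, 0 and 8 without cold replicates 1, 2 and 3. The limma counts of 0 without knockout replicate 3 and cold replicate 2 stood beside 1966 and 2289 genes at an unadjusted p under 0.05, and fitting the 2 groups alone gave 0 (1950 at an unadjusted p under 0.05). For Ucp1 the limma adjusted p was 0.0528, 0.106, 0.0943 and 0.0555 without control replicate 1, control replicate 3, knockout replicate 3 and cold replicate 2, at log2 fold changes between 6.57 and 6.91. It was also 0.0527 with the replicate number as a block and 0.145 with the 2 groups alone, and over all alternatives it ranged from 7.12e-09 to 0.949.

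Cold exposure of control mice raised markers of thermogenic fat, among them genes that also rose in the knockouts. Ucp1 rose by 6.61 ± 0.47 (SE) log2 units to 19.0 ± 0.16 (SD, n = 3), Fabp3 by 6.97 ± 0.94 and Elovl3 by 6.61 ± 1.00. Cox7a1 rose by 5.82 ± 0.34, Cpt1b by 4.25 ± 0.51 and the acyl-CoA thioesterase Acot11 by 3.72 ± 0.26 (limma adjusted p between 0.00124 and 0.0315). The row of Fabp3-ps1 rose by 7.53 ± 1.07 and the kininogen gene Kng2 by 3.41 ± 0.38. Cidea rose by 2.68 ± 0.36 (limma adjusted p = 0.0223). Dio2 stood at 2.04 ± 1.24, Ppargc1a at 1.73 ± 0.89, Prdm16 at 0.50 ± 0.18 and Ebf2 at 0.14 ± 0.16, and none of these passed (limma adjusted p = 0.38, 0.312, 0.202 and 0.642). Of the 32 members of the thermogenic list, 12 rose and 0 fell, and 18 rose when adjusted over the list alone. The list mean was 2.00 (camera adjusted p = 2.97e-16, and adjusted p = 0.243 with an estimated correlation).

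Of the 29 lists, oxidative phosphorylation held the most members that rose in the cold. In oxidative phosphorylation, 24 of 52 members rose and 0 fell, with Uqcrc1 at 2.43 ± 0.26, Cyc1 at 2.11 ± 0.30, Sdhd at 1.99 ± 0.34 and Uqcrq at 1.74 ± 0.23. Of these 52, 48 rose and 1 fell when adjusted over the list alone. In the citric acid cycle, 12 of 18 rose and 0 fell, with Suclg1 at 2.44 ± 0.27, Sucla2 at 2.22 ± 0.23, Pdhb at 2.21 ± 0.34 and Dlat at 2.01 ± 0.31. All 18 rose when adjusted over the list alone. In fatty acid oxidation, 14 of 24 rose and 0 fell, with Acaa2 at 2.73 ± 0.16, Acadvl at 2.43 ± 0.26, Hadha at 1.80 ± 0.25 and Acsl5 at 1.78 ± 0.15. Of these 24, 20 rose when adjusted over the list alone. The list means were 1.07, 1.51 and 1.03 (camera adjusted p = 8.17e-36, 3.27e-22 and 5.16e-20, and adjusted p = 0.269, 0.243 and 0.243 with an estimated correlation).

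Lipogenic genes rose in the cold as well. Of 24 members of the lipogenesis list, 5 rose and 0 fell, and 16 rose when adjusted over the list alone. Examples were the ATP citrate lyase gene Acly at 2.91 ± 0.47, Pnpla3 at 2.31 ± 0.33, the acetyl-CoA synthetase Acss2 at 1.77 ± 0.30 and the acetoacetyl-CoA synthetase Aacs at 1.42 ± 0.16. The list mean was 1.01 (camera adjusted p = 9.69e-10, and adjusted p = 0.45 with an estimated correlation). In the circadian clock list, Ciart (1.17 ± 0.19), Tef (0.61 ± 0.07) and Hlf (0.55 ± 0.10) rose, 0 of 17 fell and 4 rose when adjusted over the list alone. The list mean was 0.38 (camera adjusted p = 9.06e-06, and adjusted p = 0.168 with an estimated correlation).

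The ranked genes that fell most in the cold were the complement gene C2 (-1.78 ± 0.25), Slc1a3 (-1.53 ± 0.24), Hcar2 (-1.52 ± 0.16) and B3galt2 (-1.16 ± 0.20). They were followed by Pck1, an enzyme of glyceroneogenesis (-1.08 ± 0.18), Mid1 (-1.07 ± 0.17), the matrix glycoprotein Thbs1 (-0.93 ± 0.08) and the amino acid transporter Slc7a8 (-0.77 ± 0.13), with limma adjusted p between 0.00396 and 0.0439. Pck1 was the 1 of 21 general adipocyte genes that passed, 1 rose and 2 fell when adjusted over the list alone, and the list mean was -0.08 (camera adjusted p = 0.709). Adipoq stood at -0.44 ± 0.10, Pparg at 0.27 ± 0.22 and Lep at 1.29 ± 0.74, and none passed (limma adjusted p = 0.0946, 0.516 and 0.354). Thbs1 was the 1 of 29 extracellular matrix genes that fell, 6 fell when adjusted over the list alone, and the list mean was -0.45 (camera adjusted p = 0.000107, and adjusted p = 0.733 with an estimated correlation).

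Immune markers were lower on the cold arrays as lists, with 0 single members past the threshold. The macrophage and T cell lists stood at -0.90 and -0.77, and the B cell list had a median of -0.96. All 3 passed (camera adjusted p = 2.24e-05, 2.24e-05 and 8.03e-05, and adjusted p = 0.733, 0.808 and 0.808 with an estimated correlation). Cd68 stood at -2.26 ± 0.84, Cd8b1 at -1.41 ± 0.56 and Cd79b at -1.51 ± 0.60, with 2, 0 and 0 members lower when adjusted over each list alone. The endothelial list was higher by 0.21 (camera adjusted p = 0.013, and adjusted p = 0.819 with an estimated correlation). The cell cycle list stood at -0.19 (camera adjusted p = 0.0293, and adjusted p = 0.905 with an estimated correlation). Each had 0 members past the threshold, over all genes or over the list alone. Without control replicate 2 these last lists stood at 0.09 and -0.12 and their calls ended, at camera adjusted p of 0.209 and 0.287. The cell cycle call also ended without cold replicate 3, at 0.116 with the list at -0.16. It ended with the filter at the 75th percentile too, at 0.233, though the list stood further down, at -0.41. The skeletal muscle list stood at 0.31, -0.63 and -3.36 in cold replicates 1, 2 and 3 relative to the control mean, and did not pass (camera adjusted p = 0.0645). It passed without cold replicate 1 (1.74e-05) or cold replicate 2 (0.0234, at -1.52).

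In all, 255 of 16898 genes passed between cold-exposed and room temperature controls, 223 higher and 32 lower (limma adjusted p under 0.05), and 12 of 29 gene lists passed, 7 higher and 5 lower (0 lists with an estimated correlation, 5 at an unadjusted p under 0.05, and 6 by the fry test). The arrays of these groups did not overlap for 32.7% of the genes, against 10% by chance. Without the 3 arrays that lay between the other 2 of their group, limma called 0 genes (790 at an unadjusted p under 0.05), again with a larger spread within groups by construction. Without control replicates 1, 2 and 3 in turn the count was 90, 123 and 25, without knockout replicates 1, 2 and 3 it was 827, 985 and 74, and without cold replicates 1, 2 and 3 it was 66, 23 and 75. Fitting the 2 groups alone gave 1346. For Ucp1 the limma adjusted p was 0.816 without the 3 middle arrays and between 1.04e-06 and 0.0279 in the other alternatives.

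**Figure D2:**
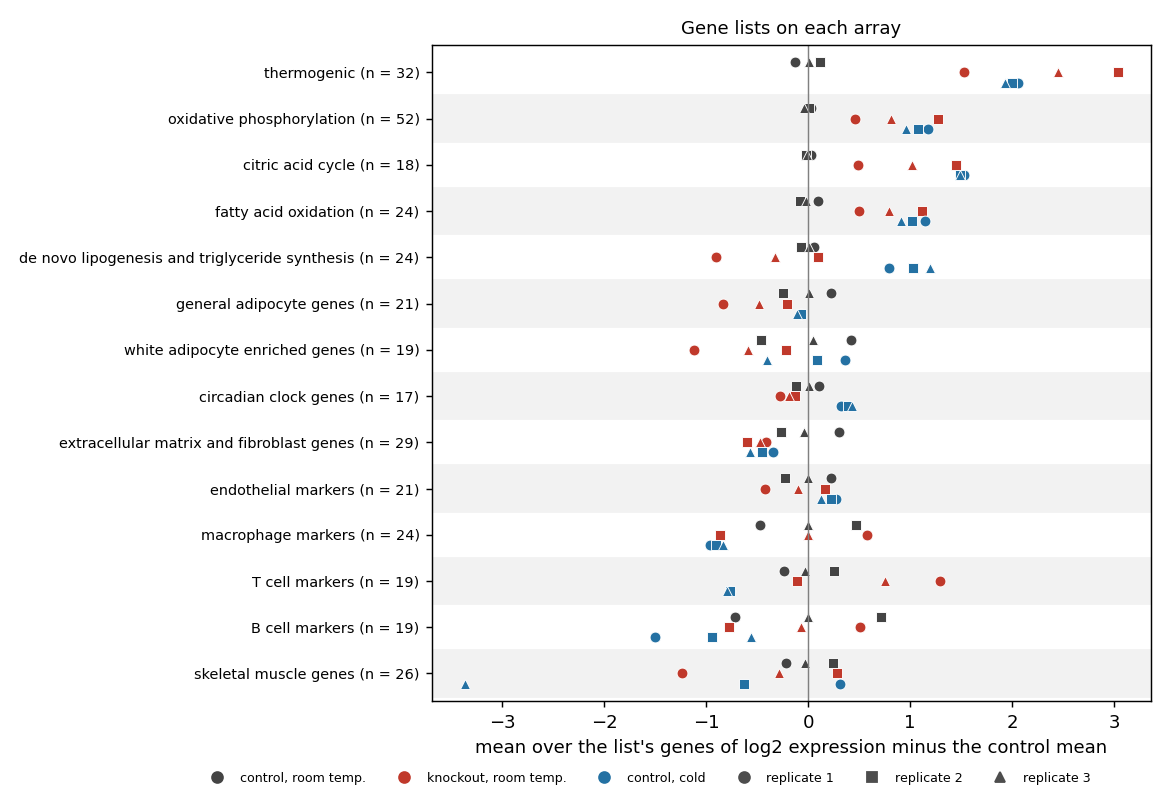
Mean over the genes of 14 lists of log2 expression minus the control mean (x axis), for each of the 9 arrays. The thermogenic list lies between 1.53 and 3.04 in the knockouts and between 1.93 and 2.06 in the cold-exposed controls, and the lipogenesis list between -0.90 and 0.10 in the knockouts and between 0.79 and 1.19 in the cold-exposed controls.

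Set against each other, cold-exposed controls and knockouts differed in lipogenic genes. Of 24 members of the lipogenesis list, 9 were higher in the cold and 0 lower, and 16 were higher when adjusted over the list alone. Acly differed by 4.08 ± 0.47 (SE) log2 units, Acss2 by 3.10 ± 0.30, Insig1, a regulator of sterol and lipid synthesis, by 2.67 ± 0.27 and the acetyl-CoA carboxylase gene Acaca by 2.66 ± 0.41 (limma adjusted p between 0.00915 and 0.027). The list mean was 1.38 (camera adjusted p = 2.28e-13, and adjusted p = 0.674 with an estimated correlation). Among the ranked genes the largest rises beside Acly, Acss2 and Insig1 were the glutathione transferase Gsta3 (2.87 ± 0.42) and Ppp1r3b, a glycogen-targeting phosphatase subunit (2.71 ± 0.37). Rbp4 (2.11 ± 0.30) was the 1 of 21 general adipocyte genes and Wfdc21 (1.19 ± 0.12) the 1 of 19 white adipocyte genes that were higher. Adjusted over each list alone, 4 and 1 were higher and 1 and 0 lower. These list means were 0.43 and 0.66 (camera adjusted p = 0.000755 and 0.000479, and adjusted p = 0.674 for both with an estimated correlation). Relative to the control mean, the general list stood at -0.83, -0.21 and -0.48 in knockout replicates 1, 2 and 3 and between -0.10 and -0.07 in the cold. The white list stood at -1.12, -0.22 and -0.59, and at 0.37, 0.09 and -0.40 in cold replicates 1, 2 and 3, so its groups overlapped.

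The thermogenic list stood at a mean of -0.34 and did not pass (camera adjusted p = 0.706), with members that went both ways, 5 higher and 6 lower when adjusted over the list alone. Ucp1 stood at -0.30 ± 0.47 (limma adjusted p = 0.715), but its values lay near the upper end of the scale in both groups, so this does not show that they were alike. Acot11 (2.10 ± 0.26) and the N-acyl amino acid enzyme Pm20d1 (1.10 ± 0.09) were higher in the cold, and Impdh1, of purine nucleotide synthesis (-2.18 ± 0.28), and the neurotrophin receptor Ntrk3 (-0.85 ± 0.12) were lower, with 28 of 32 not past the threshold. Without knockout replicate 1 the list stood at -0.75 and passed, with a camera adjusted p of 0.0172. The citric acid cycle list was higher by 0.52, with Suclg2 (0.36 ± 0.06) and Idh3g (0.34 ± 0.06) past the threshold, and fatty acid oxidation by 0.23, with Acsl5 (1.87 ± 0.15), Acaa2 (0.97 ± 0.16) and Acaa1b (0.68 ± 0.09) past it. Adjusted over each list alone, 9 and 7 members were higher and 0 and 1 lower. Oxidative phosphorylation was higher by 0.22 with 0 of 52 members past the threshold, over all genes or over the list alone. The camera adjusted p of these 3 lists were 1.14e-06, 0.000426 and 6.26e-05, and adjusted p = 0.674 for each with an estimated correlation. Without knockout replicate 1 the oxidative phosphorylation list stood at 0.03 and its call ended (camera adjusted p = 0.125). The other lists were also lowest on knockout replicate 1. Relative to the control mean, the citric acid cycle list stood at 0.49, 1.45 and 1.02 in knockout replicates 1, 2 and 3 and between 1.49 and 1.53 in the cold. Fatty acid oxidation stood at 0.50, 1.11 and 0.79, and between 0.91 and 1.15 in the cold.

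The clock list was higher in the cold than in the knockouts, with 6 of 17 members higher and 0 lower, and 12 higher and 1 lower when adjusted over the list alone. Bhlhe40 stood at 1.73 ± 0.22, Ciart at 1.54 ± 0.19, Nr1d1 at 0.92 ± 0.14 and Tef at 0.71 ± 0.07, and the list mean was 0.58 (camera adjusted p = 6.95e-08, and adjusted p = 0.0657 with an estimated correlation). The ranked genes that were lowest in the cold relative to the knockouts were the peroxidase-like Gpx8 (-2.86 ± 0.29), Impdh1, the interleukin receptor gene Il7r (-1.89 ± 0.27), Dapl1 (-1.39 ± 0.25) and Xlr3b (-1.24 ± 0.17), with limma adjusted p between 0.00965 and 0.0425. Gpx8, Impdh1 and Xlr3b rose in the knockouts against control, by 2.36 ± 0.29, 2.29 ± 0.28 and 1.24 ± 0.17, and stood at -0.49, 0.11 and 0.00 in the cold.

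Il7r and Trat1 (-1.10 ± 0.14) were the 2 of 19 T cell genes that were lower in the cold over all genes, and all 19 were lower when adjusted over the list alone. The list mean was -1.42 (camera adjusted p = 1.26e-09, and adjusted p = 0.674 with an estimated correlation). The B cell and macrophage lists stood at -0.89 and -0.80 with 0 members past the threshold, over all genes or over the list alone (camera adjusted p = 0.00264 and 0.0201, and adjusted p = 0.674 for both with an estimated correlation). Both calls ended without knockout replicate 1, at camera adjusted p of 0.116 and 0.279 with the lists at -0.58 and -0.47. The macrophage call also ended without the 3 middle arrays, at 0.0625 with the list at -0.76, and with the filter at the 75th percentile, at 0.136 with the list at -0.92. The endothelial list was higher by 0.33 and the cell cycle list stood at -0.32, with 0 members past the threshold, over all genes or over the list alone (camera adjusted p = 0.000647 for both, and adjusted p = 0.674 for both with an estimated correlation). Relative to the control mean, the endothelial list stood at -0.42, 0.17 and -0.10 in knockout replicates 1, 2 and 3 and between 0.13 and 0.27 in the cold. The cell cycle list stood at 0.40, -0.12 and 0.10, and between -0.25 and -0.14 in the cold. With the filter at the 75th percentile the cell cycle call ended, at a camera adjusted p of 0.0971, though the list stood further down, at -0.67.

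In all, 405 of 16898 genes passed between cold-exposed controls and knockouts, 210 higher in the cold and 195 lower (limma adjusted p under 0.05). With each array centred on its median the split was 226 higher and 363 lower. Without the 3 arrays that lay between the other 2 of their group, limma called 0 genes (985 at an unadjusted p under 0.05). The count was 643 and 73 without control replicates 1 and 3, then 197, 2694 and 14 without knockout replicates 1, 2 and 3, and 98, 30 and 155 without cold replicates 1, 2 and 3. Over the 3 groups together, 451 genes passed the limma F test (adjusted p under 0.05), and 0 without those 3 arrays (743 at an unadjusted p under 0.05). That count was 35 without control replicate 3, then 1094, 2110 and 38 without knockout replicates 1, 2 and 3, and 97, 37 and 86 without cold replicates 1, 2 and 3.

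The genes that passed against control in both comparisons included members of the thermogenic, citric acid cycle and fatty acid oxidation lists. Of 38 genes higher in the knockouts and 223 higher in the cold, 23 were shared, among them Ucp1, Cidea, Cox7a1, Cpt1b, Fabp3, Otop1, Ntrk3, Sucla2, Idh3b, Idh3g, Acadvl, Acaa2, Hadhb and Eci1, against 0.501 expected of independent lists. Of 24 and 32 lower genes, 7 were shared, among them B3galt2, Slc1a3, Hcar2 and Slc7a8, against 0.0454 expected of independent lists. In opposite directions 3 genes passed, Fmo1, Slc25a10 and Ttc39b, which are named here after their values were seen. In 100 simulations of unchanged groups against shared controls, a mean of 0.05 genes (at most 1) passed in simulated knockouts and 0.02 (at most 1) in simulated cold groups, and 0 passed in both. Simulated lists of the observed sizes, filled with the genes of smallest p whether or not these passed, shared a mean of 16.1 higher genes (range 9 to 25) and 4.66 lower genes (range 1 to 10), and 0.3 genes (range 0 to 2) lay in opposite directions, fewer than the 3 observed. Of the 38 genes higher in the knockouts, 33 had the same sign in the cold (34.4 in such simulated lists, range 29 to 38), and of the 223 higher in the cold, 182 had the same sign in the knockouts (196.6, range 183 to 205). Such simulated lists hold the most extreme noise, where the error of the shared controls favours the same sign. A same-sign count below their range, or an opposite count above it, therefore does not show less agreement than chance. In the direct comparison of cold and knockout, 16 of these 38 and 86 of these 223 genes also passed.

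Across all 16898 genes, which are not independent replicates, the log2 fold changes of knockout and cold correlated with a Pearson r of 0.407 and a Spearman rho of 0.159. Both comparisons use the same 3 control arrays, and 100 simulations of unchanged groups against simulated shared controls gave a mean r of 0.498 (range 0.455 to 0.545) and a mean rho of 0.445. The covariance was 0.0615 against a simulated mean of 0.0215 (range 0.0196 to 0.0249), a difference of 0.0399. The correlation lay below, and the covariance above, these simulated values. The simulations drew each gene independently, so their ranges are too narrow for genes that vary together. The simulated groups also held no effect, while an effect in 1 group alone would lower r. An r below the simulated values therefore neither shows nor excludes a shared effect. The 3 controls cannot be split into parts of 2 arrays, so part of the excess of shared genes may come from them. The excess as a whole is not called a shared effect. For the thermogenic list, fixed before the data were examined, the control arrays lay between -0.13 and 0.12 around their mean. The knockout arrays lay between 1.53 and 3.04 and the cold arrays between 1.93 and 2.06. These values argue against the shared controls as the source of this list's rise in both groups. Without knockout replicate 1 the r was 0.606 and without knockout replicate 2 it was 0.114.

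**Figure D3:**
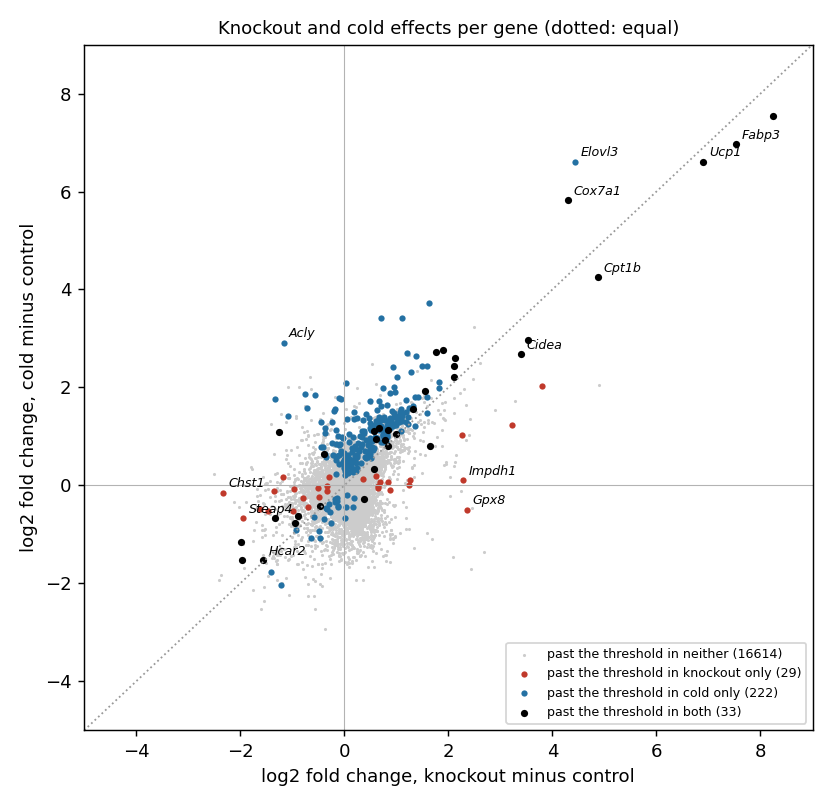
Log2 fold change of each of 16898 genes in knockouts against controls (x axis) and in cold-exposed controls against the same controls (y axis), with colours for genes past a limma adjusted p of 0.05. Of the coloured genes 33 passed in both, 29 in knockouts only and 222 in the cold only. Fabp3 lies at 7.54 and 6.97, Cox7a1 at 4.29 and 5.82 and Ucp1, whose values are near the upper end of the scale in both groups, at 6.90 and 6.61.

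In each group 1 array lay between the other 2 for most genes. Control replicate 3, knockout replicate 3 and cold replicate 2 lay between the other 2 arrays of their group for 70.5%, 75.4% and 58.5% of genes. An array named in advance would do so for 33.3% by chance. These arrays were picked for lying between, so where genes vary together their share exceeds this by the choice. Of the genes whose outer arrays differed by over 1.5 log2 units, 266, 555 and 135 in number, the middle array lay between them for 100%, 99.8% and 99.3%. The variance over genes of the middle array's distance from the mean of the outer arrays, divided by the variance of the difference between them, was 0.0732, 0.0471 and 0.147, while the same ratio for the other 6 arrays was between 1.12 and 2.32. With 1 array near the midpoint of the other 2, high ratios of those 2 follow by construction and add no evidence. Simulated separate arrays, with independent deviations for each gene, gave 0.793. A low ratio may come from genes that varied together, from arrays that depended on each other, or from both, and it does not tell these apart. For S100a8, a neutrophil gene, the knockout arrays read 9.51, 4.83 and 8.83, and for the muscle myosin Myh4 the cold arrays read 15.92, 14.56 and 7.12.

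**Figure D4:**
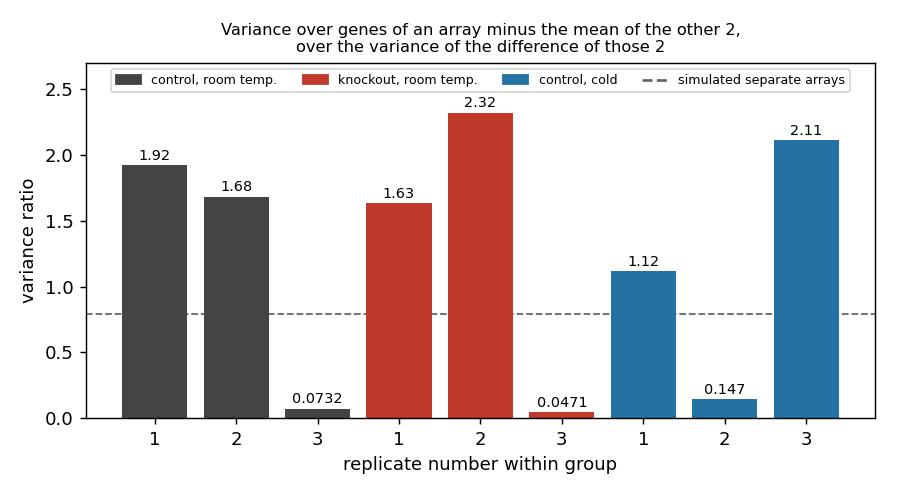
Variance over 16898 genes of each array minus the mean of the other 2 of its group, divided by the variance of the difference of those 2 (y axis), for the 9 arrays, with the value of simulated separate arrays with independent deviations for each gene, 0.793, as a dashed line. Control replicate 3, knockout replicate 3 and cold replicate 2 stand at 0.0732, 0.0471 and 0.147, and the other 6 arrays at 1.12 or more.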

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

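All values of this part were computed on transcript clusters that the comparisons of named genes left out, because the annotation gives them several gene symbols or none. Among 31243 rows tested together, 14160 were such clusters. In knockouts against controls, 17 of them were higher and 35 lower (limma adjusted p under 0.05), and in cold-exposed against room temperature controls 49 were higher and 73 lower. They stand here because this signal lies in rows on which no comparison of genes rests. The largest rises were 4.25 ± 0.39 (SE) log2 units in the knockouts (limma adjusted p = 0.0138) and 4.04 ± 0.24 in the cold (limma adjusted p = 0.00184). The annotation used here gives no single gene for either row, and no explanation was tested.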

How the results depend on the processing

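Of the calls on named genes, 0 reversed their sign in any alternative run, which leaving out arrays could not bring about for genes whose arrays did not overlap, while the counts of genes past a threshold did not hold. Of 91 calls on named genes, 86 remained after quantile normalization, 87 with arrays centred on their medians, 46 without the filter, all 82 tested with the stricter filter, 90 with the mean of all rows of a gene, 85 with all transcript clusters, 83 with the trend and robust prior, 52 with only the 2 groups, 20 with the replicate number as a block, 91 with array weights, 91 without constant rows, 0 without the 3 middle arrays and between 8 and 79 when 1 array was left out. The thermogenic list passed in 21 of 22 alternatives in both comparisons against control, with shifts from 1.99 to 2.92 in knockouts and from 1.77 to 2.51 in the cold. The exception was the estimated correlation, which left the shifts at 2.3372 and 1.9969 (camera adjusted p = 0.446 and 0.243, over ranges from 4.41e-21 and 5.04e-18) and 0 and 0 lists past the threshold (2 and 5 at an unadjusted p under 0.05). The directional fry test, which uses no preset correlation, called 4 and 6 lists. These were the thermogenic, oxidative phosphorylation, citric acid cycle and fatty acid oxidation lists in both comparisons, and the lipogenesis and clock lists in the cold. The other alternatives for lists kept the preset correlation of 0.01, so passing in 21 of 22 does not test that setting. The fits without the middle arrays and without constant rows were added after the data were seen. The number of arrays limits the precision, and differences of genes near the upper end of the scale are compressed.

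In the order knockout against control, cold against control, cold against knockout and 3 groups, an adjusted p under 0.10 gave 511, 715, 2006 and 1502 genes. An unadjusted p under 0.05 with at least 1.5-fold gave 920, 1388 and 1844, an adjusted p with 1.5-fold gave 258 for cold against knockout, and the F test at 0.01 gave 38. No filter gave 14, 130, 222 and 207, where more rows were tested. The stricter filter gave 146 for the knockouts and 708 for cold against knockout, all transcript clusters gave 118 for the knockouts, and the trend and robust prior gave 37. Array weights gave 11818, 8973, 9973 and 13282 genes and moved Zfp423 to -0.3562 (limma adjusted p = 3.66e-05, within 3.66e-05 to 0.949 over its alternatives), with weights of 1478 for knockout replicate 3, 10.9 for control replicate 3 and 1.57 for cold replicate 2, the arrays that lie closest to their group means, and the estimate of the weights stopped before it converged. Only the 2 groups gave 0 genes for the knockouts with limma (1950 at an unadjusted p under 0.05) and 1346 for the cold. Without the 3 middle arrays limma gave 0, 0, 0 and 0 genes (689, 790, 985 and 743 at an unadjusted p under 0.05), where the larger spread within groups follows from the construction. Apart from the construction of each alternative, the cause was not tested.

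Leaving out 1 array gave from 0 (knockout replicate 3 or cold replicate 2; 1966 and 2289 at an unadjusted p under 0.05 with limma) to 833 genes (knockout replicate 1), from 23 (cold replicate 2) to 985 (knockout replicate 2), from 14 (knockout replicate 3) to 2694 (knockout replicate 2) and from 35 (control replicate 3) to 2110 (knockout replicate 2). The correlation of the knockout and cold effects lay between 0.1135 without knockout replicate 2 and 0.6061 without knockout replicate 1. The skeletal muscle list turned its sign in cold against knockout, with a shift of 0.2563 without cold replicate 3 and -1.5810 without cold replicate 1 (camera adjusted p = 0.0242 and 0.0132, against 0.703 with all arrays). In the cold against control the muscle list passed after quantile normalization (0.00253), with arrays centred on their medians (0.0346), without the filter (0.0109), with the stricter filter (0.0169), with the replicate block (0.0461) and without the middle arrays (0.0482), against 0.0645. In knockouts it passed with median centring (0.0281) and with only the 2 groups (0.00136), and the macrophage list passed with median centring (0.0281). The cell cycle list passed there after quantile normalization (0.0281) and without the filter (0.0328), and the endothelial list with the stricter filter (0.0432).

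With the replicate number as a block the counts were 1, 42, 36 and 59. The numbers do not pair the samples: same-numbered control and knockout arrays correlated at -0.46, -0.46 and 0.02 in their deviations from the group means, and not every sample correlated best with its own number.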

Other observations

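Among the tests below, those of mixed RNA, of a gradient of tissue make-up, of lymphoid tissue and of a share of adipocytes as the only change were chosen after the result was seen. The lists not yet described are given here. The regulators of the thermogenic program had means of 0.07 in knockouts and 0.08 in the cold, with 0 of 27 members past the threshold; when adjusted over the list alone, 1 rose and 2 fell in knockouts. Nr4a1, an immediate early nuclear receptor, stood at 2.24 ± 0.63 (SE) and Ppargc1b at 1.87 ± 0.36 in knockouts (limma adjusted p = 0.155 and 0.078). Creatine and calcium cycling stood at 0.22 and 0.14, with Alpl at 1.05 ± 0.31 in knockouts, where 2 rose and 2 fell when adjusted over the list alone. Lipolysis and lipid droplet genes stood at 0.01 and 0.08, with Plin4 at -1.32 ± 0.25 in knockouts. BMP and TGF-beta targets stood at -0.01 and -0.09, with Gdf10 at -0.89 ± 0.56 in knockouts. Adipocyte progenitor genes stood at -0.21 and -0.16, with Cd55 at -1.33 ± 0.40 in the cold. The classical brown transcription factors, of which 3 were measured, stood at 0.15 and -0.27, and the glucocorticoid and starvation list at 0.17 and 0.27. None of these lists passed with all arrays (camera adjusted p between 0.0546 and 0.914). The glucocorticoid and starvation list passed in the cold without control replicate 1 (camera adjusted p = 0.0157, at 0.39), control replicate 3 (0.0403, at 0.30) or cold replicate 1 (0.0201, at 0.36), with the stricter filter (0.0205) and with the replicate number as a block (0.0461). The adipocyte progenitor list passed in knockouts without control replicate 2 (0.021, at -0.29), after quantile normalization (0.048) and with arrays centred on their medians (0.0361). The lipolysis list passed in cold against knockout without knockout replicate 2 (0.0392, at 0.26).

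The Schwann cell and nerve list held 1 gene that rose and 1 that fell in the cold, the calcium-binding protein gene S100b (2.65 ± 0.32, limma adjusted p = 0.015) and the myelin gene Mbp (-0.41 ± 0.07, limma adjusted p = 0.0393), with a list mean of 0.26 (camera adjusted p = 0.445). S100b is also expressed by adipocytes. In cold against knockout the list mean was 0.37 with 0 of 9 members past the threshold and 4 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0394, and adjusted p = 0.674 with an estimated correlation). The mast cell, neutrophil and eosinophil list stood at 0.46 in knockouts (camera adjusted p = 0.899), with a median of -0.005, and at -0.49 in the cold (0.0514). In the cold it passed without control replicate 1 or 3, knockout replicate 1 or 2, or cold replicate 2 or 3 (camera adjusted p between 0.0171 and 0.0481). It also passed there after quantile normalization (0.00578), with arrays centred on their medians (0.028), with only the 2 groups (0.0268), with array weights (0.0459), without constant rows (0.0491) and without the 3 middle arrays (0.0482). In cold against knockout it stood at -0.95 with 0 of 9 past the threshold, over all genes or over the list alone (camera adjusted p = 0.0345, and adjusted p = 0.674 with an estimated correlation), with S100a8 at -2.91 ± 1.12. The Schwann cell call ended without control replicate 1, knockout replicate 2 or knockout replicate 3 (camera adjusted p = 0.067, 0.0565 and 0.0554). It also ended after quantile normalization (0.0825), with array weights (0.0686), with only the 2 groups (0.0613), with the replicate number as a block (0.0561) and without the 3 middle arrays (0.0625). The mast cell, neutrophil and eosinophil call ended without knockout replicate 1, knockout replicate 3 or cold replicate 1 (0.279, 0.0575 and 0.106, at -0.57, -0.85 and -0.84) and without the 3 middle arrays (0.063). Interferon response, immediate early, erythrocyte, epithelial and sex-linked lists stood at 0.02, 0.28, 0.05, -0.03 and 0.03 in knockouts and at -0.28, 0.05, 0.13, -0.21 and -0.12 in the cold, and none passed with all arrays. The interferon list passed in the cold without control replicate 1 (camera adjusted p = 0.0276, at -0.48) and after quantile normalization (0.0332). In cold against knockout it stood at -0.30 (0.261) and passed without knockout replicate 2 (0.0072, at -0.57), after quantile normalization (0.0424) and without the filter (0.0237). Without the filter the epithelial list (0.00232) and the Schwann cell and nerve list (0.047) passed in knockouts, and by the fry test the immediate early list passed in cold against knockout (fry adjusted p = 0.0483). In cold against knockout, Klf6 was the 1 of 18 immediate early genes that was higher (0.62 ± 0.11, limma adjusted p = 0.0378). The Y-linked genes Eif2s3y, Kdm5d and Uty lay at 8.63 or more on all 9 arrays.

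In each group 1 array lay between the other 2. A mix of RNA of the outer arrays would put the middle array between them. RNA mixes before log2 is taken, so an equal mix would lie above their log2 mean for genes that differ strongly. For genes whose outer arrays differed by over 1.5 log2 units, the median position was 0.54 to 0.67 of the way from the lower to the higher array. The shares of a mix are not known, so these positions do not decide. The largest of the 3 variance ratios was 0.1473. These arrays were picked because they lie between the other 2, so a low ratio restates the pattern and does not support a mix, nor does it exclude one. Separate animals that differ along 1 gradient of tissue make-up may give the same, since the position of the middle array varied little between lists (largest SD 0.143), and the design holds no array that parts these explanations. A mix would make the spread within groups, and with it the p-values, a poor measure of the spread between animals. No biological explanation was tested.

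Thermogenic genes were lower in knockout replicate 1 than in replicate 2, with a median difference of -1.49. T cell and B cell medians were both higher in replicate 1, the smaller by 1.266 (95% bootstrap interval over list members 1.05 to 1.64), which is what more lymphoid tissue in that sample would give. The macrophage median was also higher there, by 1.31. The mast cell, neutrophil and eosinophil list had means of 1.21 and -0.49 in replicates 1 and 2 relative to the control mean. Lymphoid tissue is therefore not singled out among immune cells. A lower share of adipocytes as the only change would move the other cell types alike, while the macrophage median exceeded the endothelial median by 1.849 (interval 1.52 to 2.84). That argues against it for these 2 arrays. All these intervals resample the genes of a list and not arrays, so they do not measure the spread between animals. A lower share of adipocytes among other changes remains open, since the general adipocyte median was 0.3649 of the thermogenic one (interval 0.197 to 0.886), and 0.515 (0.198 to 1.14) without members near the upper end of the scale. A difference in recombination or in thermogenic response between the animals is a biological alternative that was not tested.

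Lipogenic genes were higher in cold-exposed controls than in knockouts, with a median of 1.17. A higher share of adipocytes in the cold arrays as the only change would move the other cell types alike. The macrophage median differed from the endothelial one by -1.222 (interval -1.64 to -0.78), which argues against it for these arrays. The interval resamples list members and not arrays, and knockout replicate 2 had a macrophage list mean of -0.87, beside -0.97 to -0.84 on the cold arrays. As a part of the cause, a higher share of adipocytes remains open, since the general adipocyte median was 0.1442 of the lipogenic one (interval 0.0644 to 0.678), and 0.439 (0.0704 to 1.09) without members near the upper end of the scale. Another time of day at collection also cannot be told apart, since Per3 differed by 1.028, the largest among the clock genes measured for this test and the 1 of them over 1, with Tef and Nr1d1 past the threshold at 0.71 and 0.92 and Arntl at -0.51, not past it. Bhlhe40 and Ciart of the clock list, which this test did not include, differed by more than Per3 in the same direction, as given above. A response to cold itself, which the design names, stays among the open explanations, untested apart from these.

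Of the 10 splits of 6 arrays into 3 against 3, 1, the real split, gave as many genes in each comparison, with 62, 255 and 405 against 0 as the highest of the others (limma), and 10 splits are too few for a share under 0.05. For the limma F test over 3 groups, 2 of 100 splits gave as many genes as the real 451, the real one included, a share under 0.05. The highest other count was 2230, in the split that kept the cold arrays together and set control replicates 1 and 3 and knockout replicate 2 against control replicate 2 and knockout replicates 1 and 3, which points to a structure of the samples that is not their group.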
